A study of Mus musculus with 24 samples.

How the data were processed

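RNA of 24 mouse lens samples was measured by sequencing of total RNA. Per the labels, epithelial RNA was prepared with the Qiagen RNeasy kit and fiber RNA with the Promega SV Total RNA system, so the kit changes with the cell type. Libraries were made with the SMARTer Stranded Total RNA-Seq Pico Input v2 kit after ribosomal depletion and read as pairs of 100 nucleotides. Per the submitters' processing notes, the authors used Trim Galore, HISAT2, SAMtools, HTSeq and edgeR on GRCm38. The versions of these tools are not given in the sources used here.

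The deposited file of each library holds whole-number read counts per Ensembl gene, which the authors made with HTSeq, and these counts were used without further scaling. Each file listed 55487 genes, and 55141 of them matched GENCODE M21 for their position on GRCm38. The HTSeq tallies of reads without a gene were left out. Reads not aligned made up between 33.6 and 65.6% of a library, at least 55.3% in fibers and at most 46.3% in epithelium, and reads without a feature between 3.19 and 18.4%. Between 11.8 and 22.7 M counts per library were assigned to genes. Where medians of lists were tested in the closing part, genes at 0 in a cell were also set to a floor of 3 counts over that cell.

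The authors' deposited tables of their comparisons give a score for each gene, a signed linear fold change per the file headers, and an FDR, which is Storey's q-value of the authors per their description sheets. From the authors' deposited tables the genes with an FDR under 0.05 were counted and set beside the calls made here, in 13 of their comparisons, and the others were not analysed here. Fractions of G and C bases per gene and gene lengths in the authors' deposited table of counts were read and entered no test. Subsets of the same tables and their repeated counts were not used here.

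Libraries were grouped by age (3 or 24 months), cell type, hours after surgery and sex as the labels give them, with 2 libraries in each of the 12 cells. Replicates of a cell were compared before use, and no pair of files held the same library. Counts were fitted in 2 models of 16 libraries and 8 cells each, the epithelium at 0 h and 24 h, and epithelium and fibers at 0 h. edgeR 4.0.16 in R 4.3.3 was used, with filterByExpr on the cells, trimmed mean of M-values factors, robust dispersion and robust quasi-likelihood F tests with 8 residual degrees of freedom. The filter left 19956 and 17697 genes. Contrasts of conditions took the mean of the sexes, differences between effects were tested as interactions, and sex contrasts were female minus male. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. SE is the absolute log2 fold change divided by the square root of F. CPM were computed with the effective library sizes, so the values of a library need not add up to 1e6.

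Of the 30 gene lists, 487 of 488 members were in the files (Ahsp was not found). The lists were crystallins, fiber cell structure, lens epithelium, epithelial-mesenchymal transition and fibrosis, cytokines and chemokines, acute-phase and endothelial-type inflammation, complement, immediate early genes, cell cycle, antioxidant genes, interferon-stimulated genes, antigen presentation, senescence, basement membrane, unfolded protein response, heat shock, cholesterol synthesis, the mitochondrial genome and glycolysis. Others were markers of macrophages, neutrophils, T and B cells, red cells, pigment cells and iris, retina, ciliary body and zonule, corneal epithelium, muscle and endothelium, and X-inactivation and Y-linked genes. No gene was in more than 1 list. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and again with the correlation estimated per list.

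Genes were named by a rule. It takes the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of at least 4 whose libraries do not overlap between the conditions (not asked of interactions or averaged sex contrasts). It adds up to 4 members per list with the smallest adjusted p, and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty in sex contrasts. A gene named in 1 contrast may be given in another, and clone names and pseudogenes were left out, except Gm23935, which was added after the values were seen. Near-identical members of families, such as Cryga to Crygf and the globins, can share reads, so their single values are uncertain. Some genes that the rule or the search for distant values brought up are not reported here. In the report, fold changes are not given for genes at 0 in both libraries of a cell of the contrast, and levels stand in their place.

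The groups, tests, lists, naming rule and all alternatives except 1 were fixed before the data were examined. The alternatives were the DESeq2 1.42.0 Wald test, relative log expression factors, no filter beyond genes at 0 throughout, a filter at a CPM of 5 in 2 libraries, no robust estimation, a replicate block, sex left out of the model, all 24 libraries in 1 fit, the edgeR exact test on the libraries compared, and each library left out in turn, where the cell left with 1 library was taken to vary like the others. The alternative of protein-coding nuclear genes alone was added after the data were seen. Labels were also shuffled over the libraries of a contrast, in all 35 or 18 possible splits or in 60 with the real one among them and the rest drawn with a fixed seed, in narrower fits of the compared libraries.

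The main model was tested on simulated data with the dispersions of these libraries. In the simulated injury in young epithelium, 50.7% of 2-fold, 82.1% of 4-fold and 92.4% of 8-fold changes were recovered, and in the simulated interaction of age and injury 9% of 2-fold and 77.6% of 4-fold changes. In simulated sex contrasts of aged epithelium at 24 h, 6% of 2-fold, 55.2% of 4-fold and 80.3% of 8-fold changes were recovered. Over the simulated contrasts, between 5 and 21 unchanged genes were called.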

Results

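RNA was sequenced from 24 mouse lens samples to follow how sex and age bear on the response of the lens to injury. The lens consists of a sheet of epithelial cells over a mass of elongated fiber cells, which are filled with crystallins, the proteins that refract light. Epithelium was collected at 0 h and at 24 h after surgery, and fibers at 0 h, from young (3 months) and aged (24 months) mice. Each of the 6 conditions held 4 libraries, 2 from males and 2 from females, and the labels call them biological replicates. The libraries held between 11.8 and 22.7 M counts (M, 1e6) assigned to genes. Levels are given as counts per 1e6 after scaling by trimmed mean of M-values (CPM), as mean ± SD over 4 libraries, and log2 fold changes as estimate ± SE, and a number beside a gene without a unit is its log2 fold change. Genes rose, fell or changed where the Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test was under 0.05. A result for a list of genes is the number of members that rose or fell, the same number adjusted over the list alone, and the camera test of the whole list against the other genes. Where a list is given in 1 direction, the count in the other was 0. Levels in the comparisons with fibers come from the fit of the 0 h libraries, whose scale differs from that of the epithelium fit, so levels of a gene are compared only within a fit. Positions are on GRCm38.

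The composition of the libraries differed by condition. Crystallin transcripts made up 11.2 ± 1.14% of the counts in young epithelium at 0 h and 3.48 ± 2.01% at 24 h, and 6.09 ± 2.28% and 2.28 ± 3.06% in aged epithelium. The shares in young and aged fibers were 17.4 ± 0.873% and 12.3 ± 0.600%. Transcripts of the mitochondrial genome made up 3.83 ± 0.250% in young epithelium at 0 h and 9.39 ± 6.52% at 24 h, and 6.38 ± 1.64% and 18.2 ± 7.46% in aged epithelium. A short gene annotated as a microRNA, Gm23935, chosen after its values were seen, took 57.2 ± 2.04% of the counts in young fibers, 38.4 ± 7.61% in aged fibers and 18.9 ± 0.368% in young epithelium at 0 h.

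The first question was how the young epithelium responds to surgery. Several genes went from nearly absent at 0 h to abundant at 24 h, among them Tnc and Cxcl3. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), which encodes a matrix protein of wounds, went from 1.36 ± 1.08 to 773 ± 176 CPM (log2 fold change 9.44 ± 0.84, adjusted p = 0.000129). Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), which encodes a chemokine that attracts neutrophils, went from 0.0765 ± 0.121 to 42.7 ± 20.5 CPM (log2 fold change 9.19 ± 0.78, adjusted p = 4.35e-05). Il1rn, the gene of the interleukin-1 receptor antagonist, went from 0.143 ± 0.177 to 32.1 ± 11.9 CPM (adjusted p = 1.27e-06). Esm1, a gene of activated endothelium, rose by 8.99 ± 0.98. Fgfr2 (ENSMUSG00000030849, chromosome 7, 130162451 to 133123350), a growth factor receptor of the lens, moved the other way, with a log2 fold change of −1.23 ± 0.21 (adjusted p = 0.00106). In all, 3741 of 19956 genes changed, 2304 higher and 1437 lower at 24 h, and 2346 of them at least 2-fold.

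**Figure D1:**
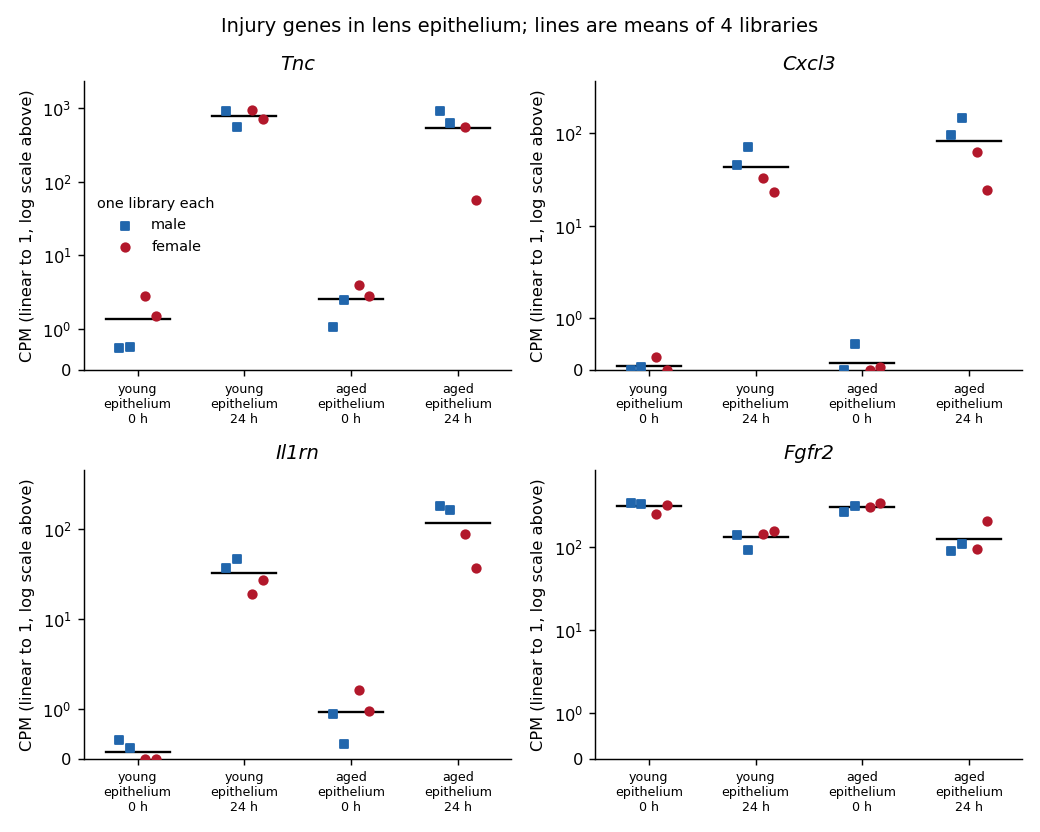
CPM on a log scale (y axis) of genes of the injury response in each epithelial library (points, squares for males and circles for females) at 0 h and 24 h in young and aged mice (x axis), with lines at the means of 4 libraries. Tnc and Cxcl3 were higher in every 24 h library than in every 0 h library of the same age, and Fgfr2 was lower.

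By groups of genes in young epithelium, the cytokine and chemokine list had 18 of 21 genes higher, and 19 higher when adjusted over the list alone (camera adjusted p = 9.41e-23, and 0.0159 with an estimated correlation). It included Il1b (4.57), the gene of interleukin-1 beta, and Cxcl2 (8.51), which encodes another neutrophil chemokine. The list of acute-phase and endothelial-type inflammation genes, such as Tnfaip2 (5.11) and the NF-kappa-B cofactor Bcl3 (5.15), had 15 of 16 genes higher, also when adjusted over the list alone (camera adjusted p = 8.7e-19, and 0.0522 with an estimated correlation). Neutrophil markers, with the granulocyte receptor Csf3r (6.42, from 0.701 ± 0.203 to 63.2 ± 27.2 CPM), had 9 of 10 genes higher, also when adjusted over the list alone (camera adjusted p = 6.49e-22, and 0.00661 with an estimated correlation). Macrophage markers, with the antibody receptor Fcgr3 (3.95) and Laptm5 (3.58), had 9 of 15 genes higher, and 10 higher when adjusted over the list alone (camera adjusted p = 3.1e-13, and 0.0346 with an estimated correlation). For the list of epithelial-mesenchymal transition and fibrosis, which holds osteopontin (Spp1, 6.37), thrombospondin (Thbs1, 4.85) and fibronectin (Fn1, 5.12), there were 17 of 30 genes higher, and 20 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.16e-15, and 0.0919 with an estimated correlation). Senescence genes, which include the urokinase gene Plau (8.01), its receptor Plaur (7.85) and the cell cycle inhibitor Cdkn1a (3.29), had 10 higher and 2 lower of 18 genes, and 12 higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.54e-05, and 0.0159 with an estimated correlation).

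Other lists rose in young epithelium with support that was lost when the correlation between genes was estimated. Immediate early genes, with the stress factor Atf3 (3.93) and the growth factor target Myc (3.91), had 15 of 21 genes higher, and 17 higher when adjusted over the list alone (camera adjusted p = 6.51e-12, and 0.194 with an estimated correlation). Cell cycle genes, with the S-phase cyclin Ccne1 (3.25) and the replication helicase gene Mcm5 (3.05), had 17 of 25 genes higher, and 21 higher when adjusted over the list alone (camera adjusted p = 1.6e-09, and 0.318 with an estimated correlation). The rise was larger in replicate 1 of each sex, with mean log2 levels of the list of 4.53 and 5.35 against 2.72 and 2.87 in replicate 2. Mki67 lay at 235.8 and 416.9 CPM in replicate 1 and at 46.6 and 29.6 CPM in replicate 2, against between 34.8 and 42.7 CPM at 0 h. Interferon-stimulated genes, with Oasl2 (3.00, adjusted p = 2.08e-07) and the RNA sensor Ifih1 (3.03), had 16 of 24 genes higher, also when adjusted over the list alone (camera adjusted p = 6.94e-13, and 0.0556 with an estimated correlation). Antigen presentation genes, with the peptide transporter Tap2 (1.85), had 9 of 17 genes higher, and 11 higher when adjusted over the list alone (camera adjusted p = 6.8e-08, and 0.0917 with an estimated correlation). Genes of the unfolded protein response, with Atf4 (1.07) and Creld2 (1.44), had 11 of 17 genes higher, and 13 higher when adjusted over the list alone (camera adjusted p = 7.42e-06, and 0.194 with an estimated correlation).

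Lists of lens genes had members that fell in young epithelium. Crystallin genes had 8 of 16 genes lower, and 14 lower when adjusted over the list alone (camera adjusted p = 1.36e-08, and 0.253 with an estimated correlation). Crygb, of the gamma-crystallin cluster whose members are near-identical and may share reads, had a log2 fold change of −4.28. The lens epithelium list had 1 higher and 4 lower of 15 genes, and 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.00387, and 0.373 with an estimated correlation). The fiber cell list, with Tdrd7 (−1.71), an RNA granule gene needed for a clear lens, had 9 of 19 genes lower, and 1 higher and 16 lower when adjusted over the list alone (camera adjusted p = 3.74e-07, and 0.318 with an estimated correlation). The basement membrane list split, with the collagen genes Col4a1 and Col4a2 lower (−1.08 and −1.35) and agrin (Agrn) higher (1.35), and the list had 3 higher and 9 lower of 19 genes, and 6 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.136, and 0.51 with an estimated correlation). Antioxidant genes split too, with the glutathione synthesis gene Gclc at −1.66 and glutathione reductase (Gsr) at 2.24, and the list had 4 higher and 4 lower of 20 genes, and 5 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.495, and 0.64 with an estimated correlation). The median and the camera test pointed downward and the mean upward. Of other tissues, red cell markers had 4 of 6 genes higher, and 5 higher when adjusted over the list alone (camera adjusted p = 0.00256, and 0.318 with an estimated correlation), and endothelium markers 3 of 8 genes higher, and 4 higher when adjusted over the list alone (camera adjusted p = 0.00537, and 0.318 with an estimated correlation). Ciliary body and zonule markers had 1 higher and 2 lower of 9 genes, and 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.125, and 0.438 with an estimated correlation). Pigment cell and iris markers had 1 higher and 1 lower of 10 genes, and 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.108, and 0.537 with an estimated correlation). Corneal epithelium markers, with a mean below 0 and a median above it, had 1 higher and 1 lower of 8 genes, also when adjusted over the list alone (camera adjusted p = 0.655, and 0.805 with an estimated correlation). Among the genes that fell most were Rgr (−3.69), an opsin gene, Oca2 (−3.27), a pigment gene, and Cilp and R3hdml (−3.44 and −3.33). The 24 h female 2 library kept 271.7 CPM of R3hdml against at most 19.3 CPM in the other 3. Leaving out 1 of the 16 epithelial libraries gave between 2089 calls (without young epithelium 0 h male 2) and 4592 (without aged epithelium 24 h female 1), with 2281 without young epithelium 0 h male 1, 2167 without young epithelium 0 h female 2 and 2243 without young epithelium 24 h female 1. Of the named calls, 26 of the 103 were lost at least once, here those of Oca2, Cilp and R3hdml.

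In aged epithelium the same comparison asked how old mice respond. Cxcl3 went from 0.139 ± 0.245 to 82.0 ± 51.2 CPM (log2 fold change 9.59 ± 0.75, adjusted p = 2.13e-05) and Tnc from 2.58 ± 1.20 to 532 ± 352 CPM (log2 fold change 7.59 ± 0.77, adjusted p = 0.000196). Slfn4 and Arg1, genes of myeloid cells, rose by 9.32 ± 0.66 and 8.87 ± 0.71. The lens genes Fgfr2 (−1.33), Six3 (−0.90), Fzd6 (−1.20) and Pax6 (−0.80), the last a master factor of eye development, fell. Changes passed the threshold for 5001 genes, 2866 higher and 2135 lower, 3134 at least 2-fold. Of the genes higher at 24 h in young epithelium, 1620 were also higher in aged epithelium against 331 expected for independent lists, and 984 were lower in both against 154. Only 3 genes changed in opposite directions.

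Lists were also tested in aged epithelium. Cytokines and chemokines, with Il1b at 4.56, had 19 of 21 genes higher, also when adjusted over the list alone (camera adjusted p = 2.85e-19, and 0.0472 with an estimated correlation). Acute-phase and endothelial-type inflammation genes, with Il1rn at 6.89 and the brake on NF-kappa-B Tnfaip3 at 2.06, had 15 of 16 genes higher, also when adjusted over the list alone (camera adjusted p = 1.19e-14, and 0.144 with an estimated correlation). Neutrophil markers, with Csf3r at 6.31 and Cxcr2 at 6.50, had 9 of 10 genes higher, and 10 higher when adjusted over the list alone (camera adjusted p = 5.24e-21, and 0.0236 with an estimated correlation). Macrophage markers, with Itgam at 4.62, had 10 of 15 genes higher, also when adjusted over the list alone (camera adjusted p = 3.75e-11, and 0.0472 with an estimated correlation). Epithelial-mesenchymal transition and fibrosis genes, with Spp1 at 5.48, had 14 of 30 genes higher, also when adjusted over the list alone (camera adjusted p = 6.95e-08, and 0.242 with an estimated correlation). Cell cycle genes had 7 of 25 genes higher, and 8 over the list alone (camera adjusted p = 0.0106, and 0.591 with an estimated correlation). Crystallins had 0 of 16 genes changed, also over the list alone (camera adjusted p = 0.035, and 0.591 with an estimated correlation). Female 2 kept a 6.84% share at 24 h, others at most 1.09%. The lens epithelium list had 9 of 15 genes lower, and 10 over the list alone (camera adjusted p = 1.66e-05, and 0.218 with an estimated correlation). Ciliary body and zonule markers, with Col9a1 at −1.75 and Wfdc1 at −2.49, had 5 of 9 genes lower, and 7 over the list alone (camera adjusted p = 6.92e-05, and 0.144 with an estimated correlation). The 24 h to 0 h ratio was lower in males for all 9 markers. Retina markers rose, with the photoreceptor genes Rcvrn at 2.33 and Pde6g at 1.99, and the list had 9 of 14 genes higher, and 11 higher when adjusted over the list alone (camera adjusted p = 9.38e-05, and 0.36 with an estimated correlation). Mitochondrial genome transcripts, with mt-Co1 at 1.32, had 10 of 12 genes higher, and 11 higher when adjusted over the list alone (camera adjusted p = 1.18e-05, and 0.323 with an estimated correlation).

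Endothelium markers had 4 of 8 genes higher, and 5 higher when adjusted over the list alone (camera adjusted p = 0.0122, and 0.36 with an estimated correlation). Pigment cell and iris markers, with Tyrp1 at −2.16, had 1 higher and 2 lower of 10 genes, also when adjusted over the list alone (camera adjusted p = 0.302, and 0.63 with an estimated correlation). Muscle markers had 0 of 8 genes changed, also when adjusted over the list alone (camera adjusted p = 0.44, and 0.56 with an estimated correlation). T and B cell markers had 0 of 6 genes changed, also when adjusted over the list alone (camera adjusted p = 0.745, and 0.804 with an estimated correlation). Immediate early genes, with Egr3 at 5.03 and Fosb at 6.18, had 14 of 21 genes higher, and 17 higher when adjusted over the list alone (camera adjusted p = 1.69e-08, and 0.242 with an estimated correlation). The stress response genes Atf4 and Asns rose by 1.22 and 2.99, and heme oxygenase (Hmox1), an antioxidant enzyme gene, by 3.17. The endothelial adhesion gene Pecam1 rose by 4.62 and the red cell gene Hba-a1, which shares sequence with Hba-a2, by 4.25. The complement inhibitor Serping1 fell (log2 fold change −1.68 ± 0.17, adjusted p = 1.46e-05), from a mean of 95.8 to 11.3 CPM in males and of 77.8 to 64.3 CPM in females. Tyrp1 went from 23.6 to 1.27 CPM in males and from 12.8 to 11.7 CPM in females. Among the genes with the lowest fold changes were Mme, Slc7a4, Cntn6, Tacr1 and Cybrd1, between −2.90 and −2.78. Mme, which encodes a peptidase of the cell surface, went from 409.9 ± 38.8 to 85.0 ± 125 CPM. The 24 h female 2 library lay apart, with 272.4 CPM of Mme against at most 27.6 CPM in the other 3. Leaving out 1 library gave between 3025 calls (without aged epithelium 0 h female 2) and 6199 (without aged epithelium 24 h female 2), with 3231 without aged epithelium 24 h female 1. Among the named calls, 28 of the 108 were lost at least once, here those of Mme, Cybrd1, Cntn6 and Tacr1.

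Whether the response differed with age was tested as the interaction of age and injury. A single gene passed, Emilin2 (ENSMUSG00000024053, chromosome 17, 71252172 to 71311978), which encodes an extracellular matrix protein (log2 fold change 2.22 ± 0.30, adjusted p = 0.0354). It went from 9.21 ± 1.12 to 45.2 ± 19.7 CPM in young and from 4.06 ± 0.971 to 97.0 ± 56.0 CPM in aged epithelium, and its call was lost in 7 of the 16 fits that left out a library. At an unadjusted p under 0.05 there were 1582 genes against 998 expected by chance, and DESeq2 called 125. Retina markers had 0 of 14 genes changed, and 10 higher when adjusted over the list alone (camera adjusted p = 3.01e-16, and 0.229 with an estimated correlation). Cell cycle genes had 0 of 25 genes changed, also when adjusted over the list alone (camera adjusted p = 4.39e-06, and 0.736 with an estimated correlation).

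**Figure D2:**
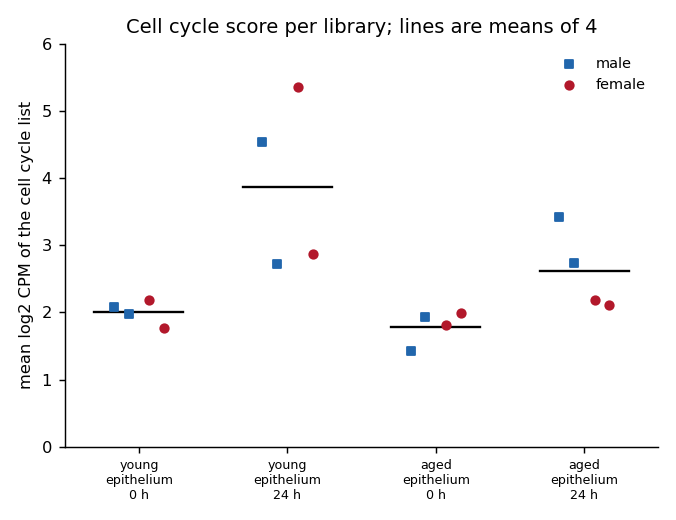
Mean log2 CPM of the cell cycle list (y axis) in each epithelial library (points, squares for males and circles for females) by condition (x axis), with lines at the means of 4 libraries. The young 24 h libraries lay between 2.72 and 5.35 and the aged 24 h libraries between 2.12 and 3.42, above the range of 1.42 to 2.18 at 0 h except for 1 aged library.

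The next question was how the epithelium differs with age at 0 h after surgery. In aged epithelium at 0 h transcripts of Crygb to Crygf had nearly gone, while interferon-stimulated genes and macrophage genes were higher. Crygd (ENSMUSG00000067299, chromosome 1, 65061872 to 65063452) was at 214 ± 104 CPM in young and 2.48 ± 3.33 CPM in aged epithelium (log2 fold change −8.43 ± 1.16, adjusted p = 0.013). Crygb and Crygc had log2 fold changes of −8.10 ± 1.01 and −8.05 ± 1.03, and Crygf went from 11.2 ± 6.15 to 0.0267 ± 0.0534 CPM, all with reads that near-identical family members may share. The leukocyte integrin gene Itgb2 rose (log2 fold change 3.81 ± 0.40, adjusted p = 0.000416), as did the macrophage genes Mpeg1 (2.44) and Ctss (2.10), the antiviral gene Oasl2 (log2 fold change 1.96 ± 0.19, adjusted p = 0.000343), the complement gene C4b (1.74), whose reads C4a may share, and the transcription factor gene Twist1 (5.65). The matrix protein gene Optc (ENSMUSG00000010311, chromosome 1, 133897199 to 133907999) rose by 1.98 ± 0.23. The axon guidance genes Dpysl3 and Sema6a fell (−2.06 and −1.82).

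With age at 0 h, 170 genes changed, 132 higher and 38 lower, 141 at least 2-fold. The exact test called 801 higher and 457 lower, DESeq2 704 genes, and fits with a replicate block 108 and without sex 88. Interferon-stimulated genes had 4 of 24 genes higher, and 15 higher when adjusted over the list alone (camera adjusted p = 1.49e-22, and 0.0236 with an estimated correlation). Among them were Ifih1 at 1.73 and Zbp1 at 3.44. Antigen presentation genes had 2 of 17 genes higher, and 8 higher when adjusted over the list alone (camera adjusted p = 4.86e-11, and 0.0384 with an estimated correlation), with beta-2 microglobulin (B2m) among them (adjusted p = 0.00823). Macrophage markers had 3 of 15 genes higher, and 9 higher when adjusted over the list alone (camera adjusted p = 1.04e-13, and 0.0236 with an estimated correlation). Complement genes had 2 of 20 genes higher, and 6 higher when adjusted over the list alone (camera adjusted p = 5.5e-07, and 0.0384 with an estimated correlation). Senescence genes had 1 of 18 genes higher, and 6 higher when adjusted over the list alone (camera adjusted p = 3.22e-06, and 0.0236 with an estimated correlation), with the growth factor binding protein gene Igfbp4 among them (adjusted p = 0.0137). Ciliary body and zonule markers had 2 of 9 genes higher, and 4 higher when adjusted over the list alone (camera adjusted p = 5.75e-08, and 0.0369 with an estimated correlation). In these the aged males stood apart, with Fbn1 at 703.4 and 628.3 CPM against 219.4 and 139.3 CPM in aged females and between 138.1 and 210.6 CPM in young libraries. The crystallin list had 5 of 16 genes lower, and 8 lower when adjusted over the list alone (camera adjusted p = 3.46e-21, and 0.0623 with an estimated correlation). Leaving out 1 library gave between 54 calls (without aged epithelium 0 h female 1) and 470 (without aged epithelium 24 h female 1), with 9 of the 16 moving the count more than 1.5 times, and 24 of the 36 named calls were lost at least once, here those of Crygd, Crygb, Crygc, Ifih1, Zbp1, B2m and Igfbp4.

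At 24 h after surgery, aged and young epithelium differed in 64 genes, 39 higher and 25 lower in aged mice. There were 12 higher and 17 lower with a replicate block, 18 and 27 with all 24 libraries in 1 fit, and 6 genes in all with sex left out of the model. The signalling adaptor gene Pik3ap1 was higher in aged epithelium (log2 fold change 1.86 ± 0.23, adjusted p = 0.0069), as were B2m (1.23), Oasl2 (1.31), the oxygen sensor gene Egln3 (1.23) and the clock gene Nr1d1 (0.99). Basement membrane collagens were lower, with Col4a5 at −1.18 and Col4a6 at −0.98, as were the receptor gene Gabrg3 (−1.38), the phosphodiesterase gene Pde3b (−1.35) and the sulfatase gene Sulf1 (−1.16). The basement membrane list had 2 of 19 genes lower, and 9 lower when adjusted over the list alone (camera adjusted p = 3.62e-09, and 0.0484 with an estimated correlation). Interferon-stimulated genes had 1 of 24 genes higher, and 13 higher when adjusted over the list alone (camera adjusted p = 3.27e-17, and 0.0484 with an estimated correlation). Macrophage markers had 1 of 15 genes higher, and 8 higher when adjusted over the list alone (camera adjusted p = 2.16e-14, and 0.0329 with an estimated correlation). Neutrophil markers had 0 of 10 genes changed, and 8 higher when adjusted over the list alone (camera adjusted p = 3.06e-09, and 0.0484 with an estimated correlation). Cell cycle genes had 0 of 25 genes changed, and 3 lower when adjusted over the list alone (camera adjusted p = 5.35e-13, and 0.213 with an estimated correlation). Fits without 1 library gave between 0 calls (without young epithelium 24 h male 1) and 689 (without aged epithelium 24 h female 2). In all, 10 of the 16 moved the count more than 1.5 times, and all 16 named calls were lost in at least 1 of these fits.

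Sex was compared next, first over the epithelium as a whole. The X-inactivation transcript Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) lay between 698.2 and 1121 CPM in the female epithelial libraries and between 0 and 18.2 CPM in the male ones, the highest male value in aged 24 h male 1. Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), on the Y chromosome, lay between 36.0 and 73.5 CPM in males and at or below 0.142 CPM in females. Eif2s3y, Kdm5d and Uty, all Y-linked, lay at or above 17.9, 28.0 and 14.2 CPM in males and at or below 0.047, 0.709 and 0.089 CPM in females. Over all 16 epithelial libraries 11 genes differed, 5 higher and 6 lower in females. Autosomal ones included the complement inhibitor Serping1 (ENSMUSG00000023224, chromosome 2, 84765387 to 84775444, log2 fold change 0.92 ± 0.12, adjusted p = 0.00254), the water channel gene Aqp4 (0.86 ± 0.13) and the mucin gene Muc5ac (−2.30 ± 0.31). Serping1 lay between 43.4 and 81.3 CPM in the 4 female and between 10.3 and 20.8 CPM in the 4 male libraries at 24 h of both ages. The calls of Aqp4, Muc5ac and Xist were lost in at least 1 fit that left out a library. The count lay between 7 calls (without aged epithelium 0 h male 2) and 1141 (without aged epithelium 24 h female 1). The list of X-inactivation and Y-linked genes had 3 higher and 4 lower of 10 genes, and 5 higher and 4 lower when adjusted over the list alone (camera adjusted p = 1.05e-65, and 2.62e-06 with an estimated correlation). The median pointed upward, and the mean and the camera test downward. Complement genes had 1 of 20 genes higher, and 6 higher when adjusted over the list alone (camera adjusted p = 3.24e-06, and 0.0994 with an estimated correlation). Interferon-stimulated genes had 0 of 24 genes changed, and 5 lower when adjusted over the list alone (camera adjusted p = 7.59e-10, and 0.144 with an estimated correlation).

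Whether the sexes responded differently was tested next in aged epithelium. The interaction of sex and injury passed for 60 genes, 58 of them with a higher 24 h against 0 h ratio in females. DESeq2 called 275 higher and 108 lower, the stricter filter left 34 genes, all 24 libraries in 1 fit 22, and the aged epithelial libraries alone 0. Serping1 fell from 89.6 and 102 CPM to 10.3 and 12.2 CPM in the 2 males, while the 2 females had a mean of 77.8 CPM at 0 h, and 47.3 and 81.3 CPM at 24 h (interaction log2 fold change 2.81 ± 0.34, adjusted p = 0.00795). Efemp1 (ENSMUSG00000020467, chromosome 11, 28853204 to 28926743), a fibulin gene of the eye's matrix, had an interaction of 4.74 ± 0.71 (adjusted p = 0.025), the fibrillin gene Fbn1 3.95 ± 0.64, the reelin gene Reln 3.33 ± 0.46, and Optc 3.23 ± 0.46. Optc lay at 468 and 642 CPM in males and 193 and 255 CPM in females at 0 h, and at 47.2 and 63.5 and 185 and 233 CPM at 24 h. Tnfaip3 had an interaction of −1.83 ± 0.32. Ciliary body and zonule markers, of which 9 of 10 passed the expression filter in epithelium, had 3 of 9 genes higher, and 8 higher when adjusted over the list alone (camera adjusted p = 3.95e-15, and 0.00749 with an estimated correlation). Leaving out 1 library gave between 1 calls (without aged epithelium 0 h female 2) and 852 (without aged epithelium 24 h female 1). Of the 16 fits, 9 moved the count more than 1.5 times, and the calls of Efemp1, Fbn1, Reln, Optc and Tnfaip3 were lost at least once.

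**Figure D3:**
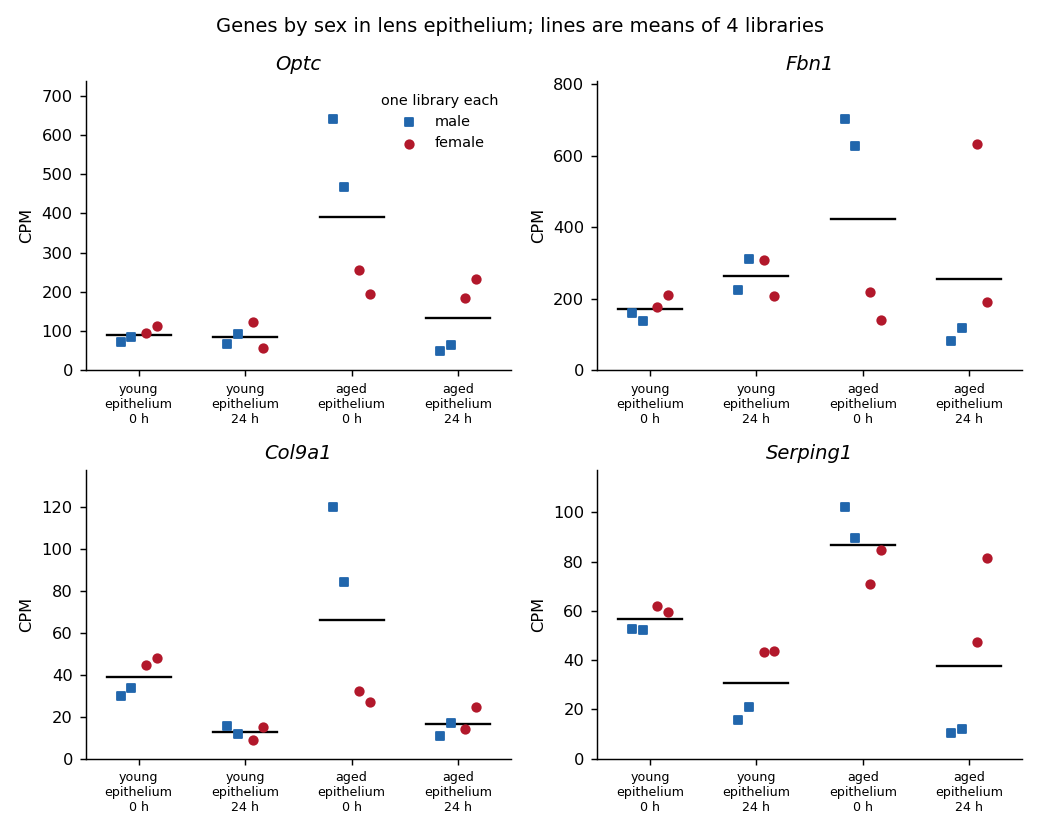
CPM on a linear scale (y axis) of Optc, Fbn1, Col9a1 and Serping1 in each epithelial library (points, squares for males and circles for females) at 0 h and 24 h in young and aged mice (x axis), with lines at the means of 4 libraries. In aged epithelium at 24 h Serping1 lay at 47.3 and 81.3 CPM in females and at 10.3 and 12.2 CPM in males.

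In young epithelium the same interaction called 0 genes with edgeR, 5 with DESeq2 and 796 (998 expected by chance) at an unadjusted p under 0.05. Within single conditions, only the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty passed in young epithelium at 0 h and at 24 h, each lower in females. Xist, with 2 libraries against 2 and at most 0.67 CPM in the young males, had an adjusted p of 0.415 and 0.356 in these tests. In aged epithelium at 0 h, 6 genes were lower in females, the same 4 and Muc5ac (−5.93 ± 0.70) and the death receptor gene Tnfrsf21 (−2.12 ± 0.28), and the last 2 calls were lost in 4 and 3 fits that left out a library. In aged epithelium at 24 h, 269 genes differed, 192 higher and 77 lower in females. The makeup of these libraries also moved with sex, with a mitochondrial share of 25.1 and 22.7% in males and 16.6 and 8.34% in females, and a protein-coding share of 45.60 and 53.05% against 65.04 and 65.77%. Among them were Serping1 (log2 fold change 2.51 ± 0.25, adjusted p = 0.00014), Efemp1 (3.74 ± 0.53), the complement protease gene C1ra (3.44 ± 0.59), C4b (1.94), the pigment gene Tyrp1 (3.18 ± 0.63) and the growth factor gene Bmp4 (3.12), all higher in females. Muc5ac (−3.36 ± 0.54), the corneal keratin gene Krt12 (−6.41 ± 1.26), Oasl2 (−1.31) and the stress factor gene Maff (−1.99) were lower. Complement genes had 3 of 20 genes higher, and 9 higher when adjusted over the list alone (camera adjusted p = 1.72e-09, and 0.0242 with an estimated correlation). Ciliary body and zonule markers had 3 of 9 genes higher, and 6 higher when adjusted over the list alone (camera adjusted p = 1.54e-06, and 0.0418 with an estimated correlation). Fits without 1 library gave between 46 calls (without aged epithelium 24 h male 1) and 2041 (without aged epithelium 24 h female 1). Again 9 of the 16 moved the count more than 1.5 times, and of the genes given here Serping1 and the Y-linked genes kept their calls in each fit.

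The comparison of fibers with epithelium at 0 h asked what sets the fiber cell apart. Cryge (ENSMUSG00000070870, chromosome 1, 65048554 to 65051149) was at 3.43 ± 1.65 CPM in epithelium and 6820 ± 618 CPM in fibers (log2 fold change 10.98 ± 1.66, adjusted p = 0.00173). Birc7, an apoptosis inhibitor gene of the fiber cell, was at 2.42 ± 1.42 and 449.8 ± 40.2 CPM (log2 fold change 7.54 ± 0.50, adjusted p = 1.9e-06). Crybb2, a beta-crystallin gene, rose by 3.21 ± 0.16, the alpha-crystallin genes Cryaa and Cryab by 2.19 ± 0.14 and 1.25 ± 0.10, the fiber membrane gene Lim2 by 5.70 ± 0.36 and Tdrd7 by 3.31 ± 0.13. The chaperone genes Hspa8 (log2 fold change 2.81 ± 0.09, adjusted p = 1.33e-18), Dnajb1 (4.66) and Hspe1 (3.71), and the antioxidant genes Sod1 (2.83) and Prdx1 (2.31) rose. Optc, Prelp, Rapgef3, Cxcl14 and Fzd7 were at 52.3 ± 10.4, 29.9 ± 10.3, 28.9 ± 2.51, 26.2 ± 2.16 and 20.6 ± 4.28 CPM in epithelium and at 0.884, 0.810, 0.970, 1.36 and 0.956 CPM on average in fibers. Serping1 (−7.11), the chemokine gene Cx3cl1 (−6.99), Pax6 (−1.94) and the proliferation gene Mki67 (−3.32) fell. In all, 9088 of 17697 genes changed, 3563 higher and 5525 lower in fibers. The median log2 fold change of all genes was −0.712, so fold changes are read against that value, and it was −0.814 with RLE, −1.077 with all 24 libraries in 1 fit, −0.435 with protein-coding nuclear genes, −0.337 in the exact test and −0.175 with the stricter filter.

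Lists in young fibers moved as follows. Crystallins had 16 of 16 genes higher, also when adjusted over the list alone (camera adjusted p = 2.17e-12, and 0.218 with an estimated correlation). Fiber cell genes had 17 higher and 2 lower of 19 genes, also when adjusted over the list alone (camera adjusted p = 3.13e-19, and 0.104 with an estimated correlation). Genes of the lens epithelium had 3 higher and 11 lower of 15 genes, also when adjusted over the list alone (camera adjusted p = 2.7e-05, and 0.147 with an estimated correlation). Heat shock genes had 7 higher and 2 lower of 11 genes, also when adjusted over the list alone (camera adjusted p = 6.85e-07, and 0.104 with an estimated correlation). Genes of the unfolded protein response, with Herpud1 at 2.94, had 11 of 17 genes higher, also when adjusted over the list alone (camera adjusted p = 2.7e-05, and 0.134 with an estimated correlation). Basement membrane genes, with Col4a2 at −2.85, had 18 of 19 genes lower, also when adjusted over the list alone (camera adjusted p = 2.56e-14, and 0.104 with an estimated correlation). Ciliary body and zonule markers, with Fbn1 at −6.22, had 9 of 9 genes lower, also when adjusted over the list alone (camera adjusted p = 1.14e-07, and 0.104 with an estimated correlation). Retina markers had 13 of 14 genes lower, also when adjusted over the list alone (camera adjusted p = 6.11e-05, and 0.286 with an estimated correlation). Glycolysis genes had 3 higher and 16 lower of 20 genes, also when adjusted over the list alone (camera adjusted p = 2.7e-05, and 0.286 with an estimated correlation), with Eno1 at −1.82 and Gapdh at 0.99. Hemoglobin genes, which differ little from each other, were higher in fibers, with Hba-a2 at 6.08, and the red cell list had 4 of 5 genes higher, and 5 higher when adjusted over the list alone (camera adjusted p = 0.0347, and 0.286 with an estimated correlation). Ighm, an antibody gene, was at 0.0380 ± 0.0458 CPM in epithelium and 7.78 ± 5.83 CPM in fibers.

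In aged mice the same comparison called 8444 genes, 3501 higher and 4943 lower in fibers, with a median log2 fold change of −0.354 over all genes. That median lay between −0.534 with all 24 libraries in 1 fit and −0.049 with the stricter filter. Fbn1 (log2 fold change −8.04 ± 0.29, adjusted p = 2.97e-12), the neurotrophin receptor gene Ntrk2 (−7.42), Igfbp4 (−7.08) and Optc (−7.01) were among the genes that fell most by the rule used here. Crybb2 (2.41), Tdrd7 (3.12), the filament gene Bfsp2 (3.89), Hspa8 (2.31), Atf4 (2.10) and the senescence gene Cdkn2b (2.71) rose. Crygd, Crygc and Crygb rose by 9.09 ± 1.26, 8.60 ± 1.21 and 8.16 ± 1.36, with means that rest largely on aged fibers female 1, which held 1800.3, 1500.1 and 1190.2 CPM against at most 112, 85.2 and 40.4 CPM in the other 3. Of the genes higher in fibers, 2758 were shared by young and aged mice against 705 expected for independent lists, 3591 were lower in both against 1543, and 65 changed in opposite directions. Crystallins had 14 of 16 genes higher, also when adjusted over the list alone (camera adjusted p = 1.21e-10, and 0.171 with an estimated correlation), and ciliary body and zonule markers 9 of 9 genes lower, also when adjusted over the list alone (camera adjusted p = 1.02e-16, and 0.0172 with an estimated correlation).

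How fibers change with age was the next question. Cryab (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636) went from 19330 ± 728 to 6902 ± 1211 CPM (log2 fold change −1.49 ± 0.10, adjusted p = 1.03e-10), Cryaa (−1.61 ± 0.14) and the beta-crystallin genes Cryba2 (−1.75 ± 0.15) and Crybb2 (−1.59 ± 0.15) fell, and Crygd went from 23260 ± 1403 to 499 ± 868 CPM (log2 fold change −6.87 ± 0.98, adjusted p = 0.00149). The gamma-crystallin genes Cryga, Crygb, Cryge and Crygf had log2 fold changes of −7.58, −7.31, −7.78 and −8.01, with reads that these genes may share and with levels in aged fibers that came mostly from female 1. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which arrests the cell cycle, was at 0 CPM in all 4 young libraries and between 24.7 and 29.5 CPM in the 4 aged ones (adjusted p = 5.81e-06). Cdkn2a and Cdkn2b, inhibitors of the same kind, rose by 4.42 ± 0.93 and 2.82 ± 0.34. Serping1 (log2 fold change 4.68 ± 0.47, adjusted p = 6.32e-08), the epithelial keratin gene Krt15 (6.58 ± 0.72), the guidance receptor gene Robo2 (3.73), the lipid scramblase gene Ano6 (3.54), E-cadherin (Cdh1, 2.39), Foxe3 (1.96) and Cx3cl1 (3.53) rose. Of 587 genes enriched in young epithelium 293 were higher in aged fibers and 5 lower. Of 1791 higher genes 1319 were higher in young epithelium than young fibers. The shared young fiber baseline can raise both. Fzd7 went from 0.956 ± 1.11 to 7.31 ± 3.96 CPM, Ifi27 from 0.173 ± 0.347 to 3.80 ± 1.61 CPM and Igkc, an antibody gene, from 0 ± 0 to 1.78 ± 0.583 CPM.

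**Figure D4:**
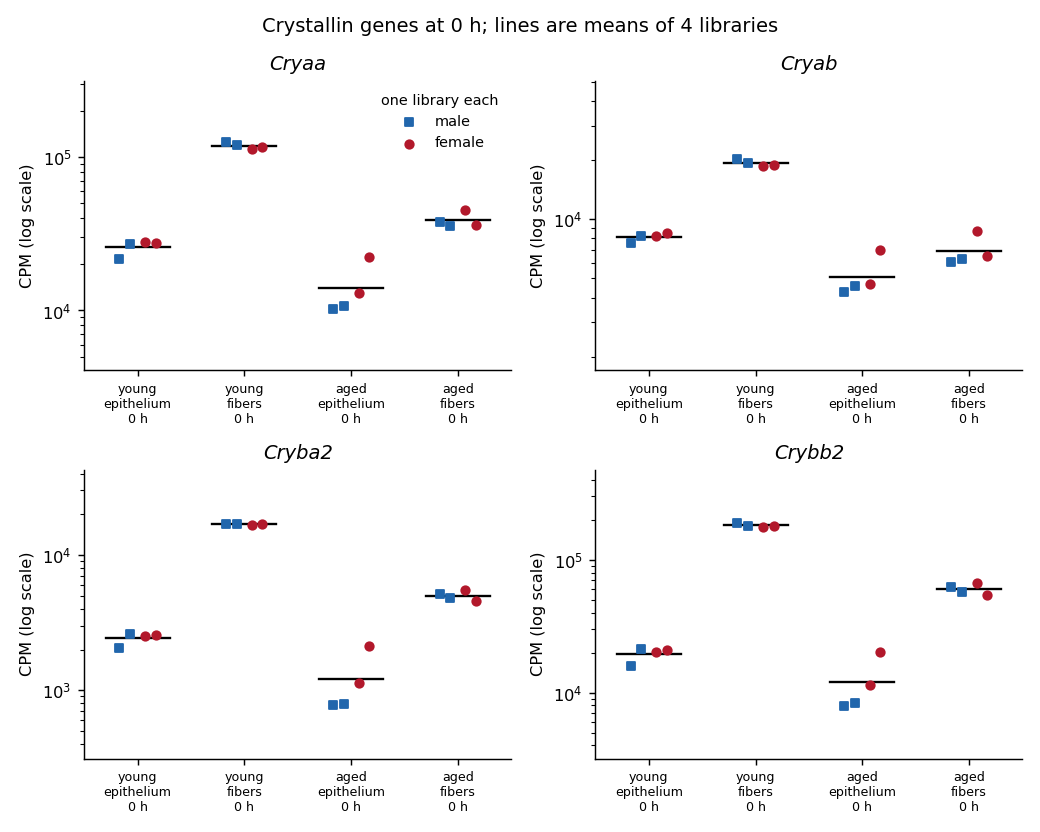
CPM on a log scale (y axis) of crystallin genes in each epithelial and fiber library at 0 h (points, squares for males and circles for females) by age and cell type (x axis), with lines at the means of 4 libraries. The genes are Cryaa, Cryab, Cryba2 and Crybb2, and Cryab was lower in every aged fiber library than in every young one.

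Age changed 3280 genes in fibers, 1791 higher and 1489 lower. The balance turned to 1565 higher and 1641 lower with RLE and 961 and 1274 in the exact test, and was stronger, 2083 and 881, with all 24 libraries in 1 fit. Crystallins had 16 of 16 genes lower, also when adjusted over the list alone (camera adjusted p = 3.72e-35, and 0.0685 with an estimated correlation). Fiber cell genes, with Grifin at −1.48 and Lim2 at −2.21, had 1 higher and 15 lower of 19 genes, and 2 higher and 15 lower when adjusted over the list alone (camera adjusted p = 3.31e-16, and 0.116 with an estimated correlation). Cholesterol synthesis genes, with Dhcr7 at −2.81, Fdft1 at −1.08 and Hmgcs1 at −1.05, had 10 of 18 genes lower, also when adjusted over the list alone (camera adjusted p = 9.02e-09, and 0.0651 with an estimated correlation). Heat shock genes, with Hspe1 at −1.88, Dnajb1 at −1.23 and Hspa8 at −0.54, had 6 of 11 genes lower, also when adjusted over the list alone (camera adjusted p = 4.5e-06, and 0.116 with an estimated correlation). Among genes of the unfolded protein response, the chaperones Hspa5 and Pdia6 fell (−1.31 and −0.92) while Atf4 rose (0.86), and the list had 1 higher and 5 lower of 17 genes, and 2 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.035, and 0.521 with an estimated correlation). Here the median and the camera test pointed downward and the mean upward. Interferon-stimulated genes had 9 of 24 genes higher, and 11 higher when adjusted over the list alone (camera adjusted p = 0.0268, and 0.526 with an estimated correlation). Immediate early genes had 7 of 21 genes higher, also when adjusted over the list alone (camera adjusted p = 0.0313, and 0.708 with an estimated correlation). Antioxidant genes split, with catalase (Cat) at −1.32, Prdx1 at −0.99 and Gstm1 at 1.35, and the list had 5 higher and 7 lower of 20 genes, and 6 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.0698, and 0.404 with an estimated correlation). Median and mean split in the same way. Glycolysis genes split too, with Hk1 at 1.40 and Gapdh at −0.64, and the list had 7 higher and 4 lower of 20 genes, and 8 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.249, and 0.805 with an estimated correlation). Corneal epithelium markers had 2 of 7 genes higher, also when adjusted over the list alone (camera adjusted p = 0.00104, and 0.22 with an estimated correlation), with Aldh3a1 at 3.22. Of the calls named for aged fibers, 20 of the 87 were lost in at least 1 of the 16 fits that left out a library, here those of Cryge, Crygf and Foxe3.

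The interaction of age and cell type called 1460 genes, 684 with a higher and 776 with a lower age ratio in fibers. With all 24 libraries in 1 fit the balance turned to 549 higher and 313 lower, and without a filter to 875 and 833. Cryab (log2 fold change −0.81 ± 0.14, adjusted p = 0.000367), the filament gene Bfsp1 (−1.86 ± 0.25), Hspa5 (−1.40), Hspe1 (−1.76), Sod1 (−1.22), Dhcr7 (−2.43), Svbp (−4.35), Ntrk2 (−4.17) and the small nucleolar RNA gene Snord15a (−3.58) had lower age ratios in fibers. Serping1 (log2 fold change 4.05 ± 0.55, adjusted p = 1.72e-05), Cx3cl1 (3.57), Cdh1 (1.88), Cdkn2b (1.96), Krt15 (4.26) and the glycolysis gene Hk1 (1.21) had higher ones. Epithelial RNA in aged fibers could raise genes such as Serping1 and Cx3cl1. Basement membrane genes had 7 of 19 genes higher, also when adjusted over the list alone (camera adjusted p = 0.0107, and 0.655 with an estimated correlation). Mitochondrial genome transcripts had 6 of 12 genes lower, and 7 lower when adjusted over the list alone (camera adjusted p = 3.12e-05, and 0.259 with an estimated correlation). Red cell markers, with Hba-a2 at −4.62, had 3 of 5 genes lower, also when adjusted over the list alone (camera adjusted p = 4.29e-05, and 0.259 with an estimated correlation). Of the genes called with age at 0 h in epithelium and in fibers, 53 were higher in both against 13 expected for independent lists, 23 were lower in both against 3, and 3 changed in opposite directions. Of 74 named calls 29 were lost at least once when a library was left out, here that of Krt15.

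Sex was also compared in fibers. Xist lay between 155.1 and 644.7 CPM in the female libraries at 0 h of both cell types and at or below 0.832 CPM in the male ones, and Ddx3y between 32.7 and 55.7 CPM in males and at or below 0.249 CPM in females. Over both ages 73 genes differed, 49 higher and 24 lower in females. Enpp2, which encodes an enzyme that makes lysophosphatidic acid, was lower in females (log2 fold change −1.94 ± 0.32, adjusted p = 0.00425), as were the collagen genes Col1a2 (−2.84 ± 0.45) and Col12a1 (−1.70 ± 0.30) and the heme synthesis gene Alas2 (−3.89 ± 0.72). Cadps2, a gene of vesicle release (2.10 ± 0.35), the glutathione transferase gene Gstm1 (0.88 ± 0.14) and the glutamine synthesis gene Glul (0.83 ± 0.16) were higher. In young fibers 38 genes differed and in aged fibers 57. Young fibers of females had more Cadps2 (3.21 ± 0.65) and Rbm3, a cold-shock gene (2.61 ± 0.55), and less Enpp2 (−2.47 ± 0.50) and Map2k1 (−1.73 ± 0.29). Aged fibers of females had more Prelp (4.66 ± 0.64), Top2a (4.51 ± 0.80) and Cxcl14 (2.35 ± 0.45), and less Col12a1 (−3.15 ± 0.45) and Alas2 (−5.47 ± 1.07). Red cell markers had 2 of 5 genes lower, and 5 lower when adjusted over the list alone (camera adjusted p = 7.73e-12, and 0.056 with an estimated correlation). Fits without 1 library gave between 43 calls (without aged fibers 0 h male 1) and 204 (without young fibers 0 h male 2) over both ages. In young fibers they gave between 28 calls (without aged epithelium 0 h male 1) and 128 (without young fibers 0 h male 2), and in aged fibers between 14 calls (without aged fibers 0 h male 1) and 149 (without aged fibers 0 h female 2). The calls of Col12a1, Alas2, Cadps2 and Glul over both ages, Cadps2, Rbm3 and Enpp2 in young and Prelp, Top2a, Cxcl14, Col12a1 and Alas2 in aged fibers were lost at least once.

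The authors' own tables were set beside these counts. In the authors' deposited table of injury in young epithelium, 4281 genes had an FDR under 0.05, and 3497 were called in both, all in the same direction. In the authors' deposited table for aged epithelium, 5599 genes passed and 4591 were called in both. For age at 0 h and at 24 h the authors' deposited tables listed 422 and 142 genes, of which 109 and 43 were called in both. The authors' deposited table of age in fibers listed 3716 genes with 3004 called in both, and those of fibers against epithelium listed 11239 in young and 9833 in aged mice with 8936 and 7969 called in both. For sex in aged epithelium the authors' deposited tables listed 107 genes at 0 h and 680 at 24 h, with 5 and 269 called in both. All genes called in both had the same direction in each of these tables.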

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

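The shuffles of labels were planned in advance, and the 9 other tests below were chosen only after the result was seen. In 177 groups of 4 libraries a fixed rule for 1 distant value was applied, and 34 values stood apart from the other 3 of their group. Chance alone flags about 1 in 20 groups, which is about 9 here.

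In library measures, young epithelium at 0 h male 1 had 16.25 M assigned counts (others 19.277 to 19.493) and a crystallin share of 9.461% (others 11.546 to 11.9). Young epithelium at 24 h female 2 had 23677 genes detected (others 21755 to 21947). In young epithelium at 0 h female 1, 41.022% of reads were not aligned (others 37.443 to 38.039), and in aged epithelium at 0 h female 2, 10.747% had no feature (others 13.666 to 14.082). Aged epithelium at 24 h female 2 had a crystallin share of 6.838% (others 0.3 to 1.089).

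Aged epithelium at 24 h female 2 stood apart in 7 values, the most of any library. Besides its crystallin share, its CPM lay far from the other 3, among others, for Mme (272.35, others 16.42 to 27.639), Slc7a4 (28.337, others 1.299 to 4.562), Cntn6 (18.336, others 1.373 to 2.273), Tacr1 (88.722, others 4.281 to 12.905) and Cybrd1 (93.723, others 6.91 to 12.094). Young epithelium at 24 h female 2 stood apart, among others, in CPM of Cilp (39.122, others 2.762 to 4.251), R3hdml (271.745, others 9.261 to 19.298) and Oca2 (30.55, others 2.166 to 4.728).

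Aged fibers female 1 had far higher CPM of gamma crystallins than the other aged fibers, with Cryge at 552.464 (others 3.215 to 4.475), Crygf at 282.396 (others 1.478 to 2.577), Crygd at 1800.26 (others 39.971 to 112.292), Crygc at 1500.121 (others 38.315 to 85.169), Crygb at 1190.188 (others 11.944 to 40.414) and Cryga at 14.287 (others 0 to 0.407). Young fibers male 1 had Crygb at 17640.062 (others 15393.074 to 15730.561). In young epithelium at 0 h male 1, Cryge was 0.978 (others 3.883 to 4.423) and Crygf 1.187 (others 7.825 to 8.569), and in aged epithelium at 0 h female 2 Crygf was 0.062 (others 0).

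The levels of crystallins, Birc7, Optc, Prelp and Rapgef3 given here are from the fit of epithelium and fibers at 0 h and the others from the epithelium fit, and the scales of the fits differ. The remaining distant CPM values were smaller in reach. At 0 h they were Cxcl3 in aged epithelium male 2 (0.504, others 0 to 0.053), Mme in aged epithelium female 1 (351.871, others 426.306 to 431.592), Myb in young epithelium female 2 (15.213, others 7.958 to 8.465), and Dpysl3 (58.471, others 21.394 to 25.993) and Rapgef3 (25.124, others 29.739 to 30.412) in young epithelium female 1. In young fibers they were Birc7 in female 1 (389.559, others 467.255 to 471.405), Optc in male 2 (3.537, others 0) and Prelp in female 2 (3.241, others 0). No library was left out for these values.

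The 3 interactions with called genes were listed as well, because an effect differed between groups in them: age and injury (1 gene), sex and injury in aged epithelium (60 genes), and age and cell type (1460 genes).

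The interaction of sex and injury in aged epithelium (60 genes) was marked by ciliary body and zonule genes, whose median log2 difference, female minus male, was −0.929 at 0 h and 1.749 at 24 h, with Fbn1 at 0 h at 703.427 and 628.347 CPM in males and 219.393 and 139.346 CPM in females. The pigment cell and iris markers, which had not been used to find this, had a median log2 difference of 1.355 at 24 h (quartiles 0.765 to 1.746), as RNA of ciliary body and iris tissue in the female libraries predicts, but of −0.238 at 0 h, with members on both sides of 0. Corneal markers at 24 h (median −2.595) cannot test a lower lens RNA share, as Krt12 was already lower in aged females at 0 h. The library aged epithelium 24 h female 2 stays open as the only source, since its cell has no replicate without it. Ciliary tissue carried along at dissection could explain the 24 h part, and its bearing on the 0 h part stays open. A lower share of lens RNA stays open, as does a biological difference between aged females and males, untested here.

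The lower crystallins and other age differences in fibers were weighed against the makeup of the libraries. A few RNAs taking most of the counts stay open, as the test on protein-coding nuclear genes (3078 called) kept the crystallins. Epithelial RNA in the aged fiber libraries was argued against for the crystallins, whose median of −2.657 lay below the −0.337 that dilution would give, and for 142 genes that were higher in aged fibers and were already higher in young fibers than in young epithelium. For genes higher in young epithelium the same explanation stays open, since 293 of 587 epithelium-enriched genes were higher in aged fibers and 5 lower. These may come from epithelial RNA, the shared baseline or an untested age difference within fibers.

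Cell cycle genes after injury had a mean score of 3.87 in young and 2.62 in aged epithelium at 24 h. Spread between libraries could give such a difference, with an exact two-sided permutation p = 0.171 where the smallest possible was 0.0286. Aged epithelium 24 h female 2 was not alone in a low score (2.12, female 1 2.19). Whether it lowered the count called after injury (7, young 17) stays open, as its cell has no replicate without it. Whether age lowers the response stays open.

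Shuffled labels were used to ask whether chance can be excluded, in fits of the compared libraries, with sex only in the sex contrasts, so counts of the real labels can differ from the report. Among 35 splits, chance was excluded for injury in young (4221 genes, highest other split 5) and aged epithelium (2492 and 3), age in epithelium at 0 h (832 and 80), fibers against epithelium in young (8865 and 3) and aged (7910 and 3), and age in fibers (2176 and 4). In each, 1 split, the real one, gave as many genes. Among 60 splits it was excluded for age and cell type (1216 and 987) and sex in epithelium (11 and 10), where again 1 split, the real one, gave as many, by a narrow margin. Of the 11 sex calls, 7 are genes of the X and Y chromosomes that follow from the sex of the animals, so this says nothing on the 4 autosomal ones.

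Chance was not excluded for age and injury (0 genes, highest other split 249, all 60 as large) or age in epithelium at 24 h (0 genes, highest other split 613, all 35 as large). With 0 genes for the real labels every split was bound to be as large, so this says nothing on the genes called with sex in the model. The median of the other splits was 0 in both, so only some splits called many genes, which points to a structure of the samples that was not tested. Too few splits exist for sex in fibers (18 genes, highest other 23, 2 of 18 as large), sex and injury in young epithelium (0 and 5, 18 of 18 as large) and sex and injury in aged epithelium (0 and 7, 18 of 18 as large).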

How the results depend on the processing

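The alternatives below were planned in advance except protein-coding nuclear genes alone, which was chosen only after the result was seen. Counts are of called genes, and the cause of each change was not tested unless stated.

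Injury, fibers against epithelium, and age in fibers kept their counts within 1.5 times under every model, filter and test tried. Of 780 named gene results, DESeq2 kept the direction and the side of the threshold of all 780, relative log expression factors of 773, no filter of 769, no robust estimation of 760 and all 24 libraries of 603. The stricter filter kept 732 of 758, the replicate block 584 of 674, sex left out 566 of 664, protein-coding nuclear genes 734 of 745 and the exact test 584 of 636. Leaving out 1 library kept 11150 of 12480, with 1328 weaker and 2 reversed. Of 229 counts of called genes in lists, 182 stayed within 1.5 times with DESeq2, 222 with relative log expression factors, 168 with no filter, 195 with the stricter filter, 212 with no robust estimation, 211 with protein-coding nuclear genes and 152, with 71 weaker, with all 24 libraries. The replicate block kept 146 of 194, sex left out 149 of 190, the exact test 134 of 190, and leaving out 1 library 2898 of 3664, with 639 weaker.

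DESeq2 called more genes for age and injury (125), age in epithelium at 0 h (704) and at 24 h (436), sex in epithelium (283), sex and injury in young (5) and aged epithelium (383), sex in young epithelium at 0 h (13) and 24 h (18), in aged epithelium at 0 h (41) and 24 h (1111), and sex in all (381), young (241) and aged fibers (337).

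Without a filter on low counts, the same results gave 557, 1123, 845, 828, 273 and 741 genes, then 102 and 251 for sex in young epithelium, 260 and 1413 in aged epithelium, and 297, 172 and 271 in fibers. The stricter filter, by which fewer genes were tested, gave 0 for age and injury, 32 for age at 24 h and 34 for sex and injury in aged epithelium.

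The 1 gene of age and injury was not called without robust estimation (0), with a replicate block (0), with sex left out (0), with protein-coding nuclear genes (0) or with all 24 libraries (0). Age at 0 h and at 24 h gave 108 and 29 genes with a replicate block, and 88 and 6 with sex left out.

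With all 24 libraries in 1 fit, age and cell type gave 862, sex in epithelium 26, sex and injury in aged epithelium 22, sex in fibers 33 and sex in aged fibers 24. The exact test, which used fewer samples, gave 1258 for age at 0 h, 42 and 11 for sex in young epithelium at 0 h and 24 h, 285 and 151 in aged epithelium, and 5 in young fibers. Relative log expression factors moved no count by more than 1.5 times.

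Single genes reversed in direction 4 times among the named results. Kdm5d after injury in aged epithelium changed sign to 0.018 with sex left out and 0.005 in the exact test, with 0 CPM in both 24 h females. In fibers against epithelium in aged mice, Hba-a1 (2.86) became −0.765 and Eif2s3y (2.696) became −0.577 without aged fibers female 1. Their highest values without 1 library were 3.403 and 3.549.

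Leaving out 1 library also leaves out samples, and it moved some counts by more than 1.5 times. The libraries whose absence did so are named with the count without each, and the time is that of the epithelium. For age and injury they were aged 0 h male 1 (2), male 2 (0), female 1 (0), female 2 (2), aged 24 h male 2 (3), female 1 (99), female 2 (180). The young libraries were 0 h male 1 (0), female 1 (0), female 2 (0), 24 h male 1 (2), male 2 (5), female 1 (0), female 2 (23). For age in epithelium at 0 h they were aged 0 h male 1 (73), male 2 (101), female 1 (54), aged 24 h female 1 (470), female 2 (445). Young libraries that did so were 0 h male 1 (73), male 2 (60), female 1 (92), female 2 (83). For age in epithelium at 24 h they were aged 0 h male 1 (35), male 2 (35), aged 24 h male 1 (35), male 2 (16), female 1 (198), female 2 (689). Among young libraries they were 24 h male 1 (0), male 2 (140), female 1 (2), female 2 (122). For sex and injury in aged epithelium they were aged 0 h male 1 (5), male 2 (29), female 1 (7), female 2 (1), aged 24 h male 1 (11), male 2 (92), female 1 (852), female 2 (204). The young libraries were 24 h male 1 (98). For sex in aged epithelium at 24 h they were aged 0 h male 1 (154), male 2 (157), female 2 (166), aged 24 h male 1 (46), male 2 (135), female 1 (2041). Young libraries that did so were 0 h male 1 (141), male 2 (142), female 2 (168).

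For sex in epithelium they were aged 0 h male 2 (7), aged 24 h male 2 (17), female 1 (1141), female 2 (32). Among young libraries they were 24 h male 1 (79). For injury in aged epithelium, where the highest count was 6199, they were aged 0 h female 2 (3025), aged 24 h female 1 (3231). For sex and injury in young epithelium they were aged 24 h female 1 (1), female 2 (1). The young libraries were 24 h male 1 (1). For sex in aged epithelium at 0 h they were aged 24 h female 1 (11), female 2 (11). For sex in young epithelium at 24 h they were aged 24 h female 1 (17), female 2 (14). Young libraries that did so were 24 h male 1 (153).

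For injury in young epithelium, where the highest count without 1 library was 4592, they were young 0 h male 1 (2281), male 2 (2089), female 2 (2167), young 24 h female 1 (2243). For sex in aged fibers they were aged 0 h male 1 (35), male 2 (35), aged fibers male 1 (14), female 2 (149). Among young libraries they were fibers male 1 (140), male 2 (139), female 1 (120), female 2 (122). For sex in fibers they were aged fibers male 1 (43), female 2 (121). The young libraries were fibers male 2 (204), female 2 (130). For sex in young fibers, where the lowest count was 28, they were aged fibers female 1 (68), female 2 (67). Young libraries that did so were fibers male 1 (59), male 2 (128), female 1 (66), female 2 (71).

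Depth limits the low end. With between 11.8 and 22.7 M assigned counts, genes below about 1 CPM rest on few reads, and with 2 libraries per cell, 6% of simulated 2-fold sex differences were recovered in aged epithelium at 24 h.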

Other observations

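Muc5ac was nearly absent from young epithelium at 0 h in both sexes, with CPM of 0.508 and 0.951 in females and 0.413 and 1.096 in males. At 24 h it was 63.016 and 65.63 in young females and 58.981 and 59.417 in young males. In aged males it was already 16.013 and 18.705 at 0 h and 36.545 and 79.217 at 24 h, whereas aged females had 0.095 and 0.48 at 0 h and 3.101 and 8.227 at 24 h.

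Krt12, a gene of corneal epithelium, was 10.424 and 11.551 CPM in aged male epithelium at 0 h and 5.622 and 19.885 at 24 h, against 0.213 and 0.567 and then 0.054 and 0.221 in aged females. In young epithelium at 24 h it was 3.06 and 3.591 in females and 1.192 and 16.583 in males.

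On the first principal component of the epithelium libraries, which held 39.3% of the variance, aged epithelium at 24 h female 2 lay at 7.7, and the other aged libraries at 24 h lay at 107.3, 118.8 and 130.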
